A study of Mus musculus with 24 samples.

How the data were processed

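Gene expression was measured by oligo-dT-primed, stranded RNA sequencing in 24 libraries of mouse Lys-GFP-ER-HoxA9 cells: 2 libraries at each of 10 times after estradiol withdrawal and 1 R07 library at each of 4 times. The deposited table holds raw whole-number counts per gene for each library, with no normalization; per the labels, the authors' processing used STAR 2.4.2a, Picard and the mm10 build, and the labels state neither the counting program, the strand setting nor the annotation release. Of 45323 lines in the table, 4 name no gene (unmapped, multimapping, ambiguous and outside annotated genes), 45318 carry Ensembl gene identifiers and 1 carries another identifier. The 4 were kept out of library sizes and tests. Symbols and mm10 positions were taken from reference annotation for 44585 Ensembl genes, which hold 99.9% of Ensembl gene counts; 733 had no symbol and 56 symbols were shared by more than 1 identifier. Across libraries, multimapping reads were 6.23 to 8.72% of all reads, those outside annotated genes 3.88 to 6.48%, unmapped reads 1.53 to 2.29% and ambiguous reads 1.08 to 1.25%.

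Counts were scaled by TMM factors and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), after filterByExpr, with quasi-likelihood tests and Benjamini-Hochberg adjustment over all genes tested; a gene was called at an adjusted p under 0.05. The 20 withdrawal libraries were fitted together with time as a factor (14615 genes), and each time was compared with 0 h. R07 was compared with the 8 withdrawal libraries at the same 4 times with time as a factor and an arm term (13641 genes), so its spread holds both replicate spread and any change of the difference with time. R07 was also compared with the 2 libraries at 0 h as 1 arm (13704 genes); differences between the R07 times enter that spread. No test was made within a single R07 time, which has 1 library. Levels per library are CPM with TMM-scaled library sizes, and components and correlations use log2 CPM with a prior count of 2. Pearson and Spearman correlations across genes carry no p-value.

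Gene lists, 35 in all, were written before the data were examined, and so were the comparisons, the alternatives to be tried and the rule for named genes. The lists were tested with camera on log2 CPM with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry; fry is self-contained, and asks whether the genes of a list move one way on balance without a comparison with other genes. Lists with at least 5 measured genes were tested, with adjustment over the lists of a comparison. Counts of members called are given over all genes and adjusted over the list alone. They covered granule contents, neutrophil, monocyte and surface receptor genes, transcription factors, cell cycle, biosynthesis, stress, inflammation and metabolism, 7 other cell types, mitochondrially encoded transcripts and RNA quality. Genes named in every comparison were 22 anchors of the system, and for each comparison the 8 highest and 8 lowest log2 changes among called genes with a mean log2 CPM of at least 3, all libraries of the compared group on one side of all those of the other (for R07 against withdrawal, within each of the 4 times and on the same side), and a gene name that is not a clone or pseudogene name. List members named as examples, the genes named for R07 against 0 h, where the rule gave none, and the courses over intermediate times were chosen after their values were seen. A gene without reads in a group is given by its levels, or as a bound against 3 counts over the group; this bound covers counting error only.

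Replicate libraries had a Pearson correlation of at least 0.992 on the log2 scale, and their counts spread 5.84 (8 h) to 45.8 (96 h) times more than counting error alone. The tests were checked on simulated counts. There, 2-fold changes were recovered in 98, 100 and 99% of genes for 120 h, R07 against withdrawal and R07 against 0 h. Of the calls, 7.48, 6.10 and 9.95% were false, and camera called 10 of 10 shifted lists and 0 of 15 unshifted ones. The simulated libraries lay around the 0 h means, with the same change at all R07 times and genes drawn independently. The check thus does not cover change between R07 times or genes of a list moving together. The alternatives tried were RLE normalization, no filter on low counts, DESeq2 1.42.0, other sets of libraries in the fit, a linear trend over R07 hours, leaving out each library in turn, other list tests, a block on the column letter, and for the correlation another prior count, ranks and a minimum level. The line with another identifier was left out of the gene lists, and its identity is not stated in the labels.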

Results

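RNA was sequenced from mouse myeloid progenitors that carry an oestrogen receptor fusion of the homeobox protein HoxA9 and a lysozyme-GFP reporter, a line named Lys-GFP-ER-HoxA9 and made on the C57Bl/6 background. In such lines estradiol in the medium, here 0.5 uM, keeps the fusion active and the cells immature, and taking estradiol away starts myeloid differentiation. The time course held 20 libraries, with 2 at each of 10 times (0, 4, 8, 12, 24, 36, 48, 72, 96 and 120 h after withdrawal). A further 4 libraries came from the same cells treated with R07, a compound known here only by its code, with 1 library each at 12, 36, 72 and 120 h. The labels do not say whether estradiol was present during R07 treatment, and the R07 libraries have no replicates. Counts assigned to genes ran from 36.7 to 49.6 M per library (median 43.7 M), which was 82.7 to 85.7% of the reads, and 16995 to 17887 genes had at least 1 count. The mitochondrially encoded genes took 0.801 to 1.96% of the gene counts, and the 10 most abundant genes took 4.21 to 7.84%. Levels are given as CPM, counts scaled to library size, as the mean ± SD of 2 libraries for withdrawal and as single values for R07. Changes are log2 values ± SE, and a value ± SE in parentheses after a gene symbol is such a change. Adjusted p-values come from edgeR models fitted across all genes and measure only the spread between these libraries, since the labels do not state that replicates were separate cultures. Gene positions are on mm10.

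Across 15371 genes the first principal component held 65.0% of the variance and the second 15.3%. The withdrawal libraries moved along the first component from -87.8 and -86.6 at 0 h to 213 and 204 at 120 h. The R07 libraries stayed near the early withdrawal times on that component, at -73.1 (12 h), -42.2 (36 h), -34.3 (72 h) and -52.5 (120 h). On the third component (5.42% of variance) R07 went from 3.17 at 12 h to -50.9, -74.5 and -66.1 at the later times, whereas the withdrawal libraries ranged from -24.01 to 32.2.

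**Figure D1:**
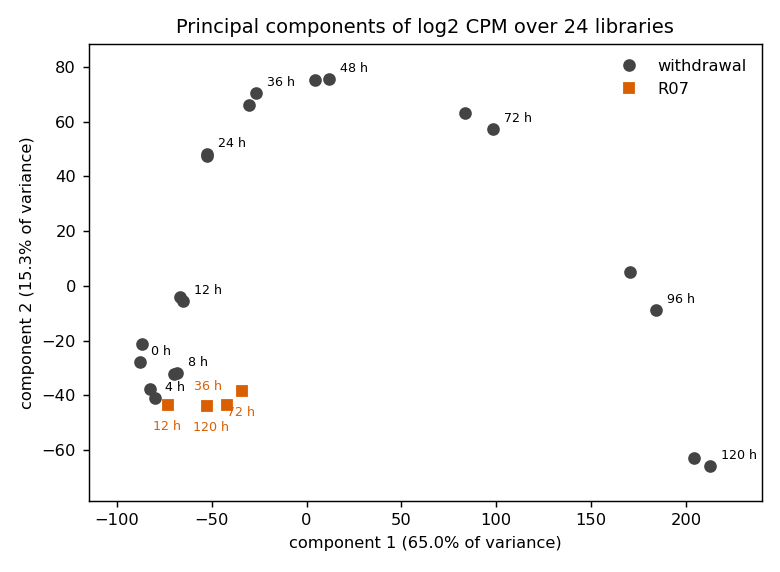
Each of the 24 libraries placed by its first (horizontal axis, 65.0% of variance) and second (vertical axis, 15.3%) principal component of log2 CPM. Grey circles are withdrawal libraries, with 2 per time, and orange squares are the R07 libraries; withdrawal ran from left to right up to 213 at 120 h, and R07 at 120 h lay at -52.5.

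The number of genes that differed from 0 h grew over the withdrawal course apart from a dip at 12 h, and at 120 h close to even numbers lay on each side. Over the whole course 13311 of 14615 genes tested (91.1%) changed at some time. Against 0 h, 1717 genes were called at 4 h (1055 higher, 662 lower), 3201 at 8 h (1887 higher, 1314 lower), 2340 at 12 h (1345 higher, 995 lower) and 4076 at 24 h (1978 higher, 2098 lower). The counts then went to 5981 at 36 h (3017 higher, 2964 lower), 7683 at 48 h (3769 higher, 3914 lower), 10169 at 72 h (5103 higher, 5066 lower), 11308 at 96 h (5663 higher, 5645 lower) and 11671 at 120 h (5786 higher, 5885 lower). Changes of at least 2-fold were called for 437 genes at 4 h, 1454 at 24 h and 7957 at 120 h. Single libraries moved the early counts by more than 1.5 times: at 4 h the count was 815 without the second 0 h library (B) and 861 without the first 4 h library (A). At 8 h it was 1494 without 0 h library B, 1531 without 8 h library A and 1886 without 8 h library B; at 12 h it was 1445 without 0 h library B and 1476 without 12 h library B; at 24 h it was 2681 without 0 h library A and 2699 without 24 h library B. At 4 h DESeq2 called 1964 genes, 1008 higher and 956 lower, against the 1055 and 662 of edgeR.

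**Figure D2:**
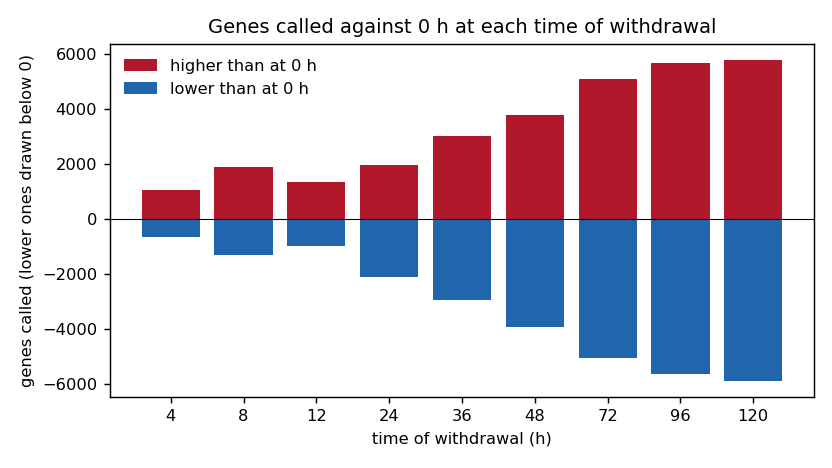
Genes called against 0 h (vertical axis, number of genes at adjusted p under 0.05, higher above 0 and lower below) at each time after withdrawal (horizontal axis, hours). The bars reach 1055 higher and 662 lower genes at 4 h and 5786 higher and 5885 lower at 120 h.

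The comparison of 4 h with 0 h asks which transcripts move first once estradiol is gone. Transcription factor genes were among the largest increases: Atf3, a stress-responsive factor (ENSMUSG00000026628.10, chromosome 1, 191170296 to 191218039, minus strand), rose by 5.11 ± 0.66 on the log2 scale, from 0.0331 ± 0.011004 to 1.26 ± 0.421 CPM (adjusted p = 1.79e-05). Jun, a subunit of AP-1, rose by 2.88 ± 0.27 (adjusted p = 3.76e-07). Gfi1b, a repressor of erythroid and megakaryocytic cells (ENSMUSG00000026815.11, chromosome 2, 28609450 to 28621982, minus strand), rose by 2.87 ± 0.19, from 2.63 ± 0.1402 to 19.3 ± 4.02 CPM (adjusted p = 4.70e-09). Irf8, a factor of monocyte and dendritic cell development (ENSMUSG00000041515.6, chromosome 8, 120736358 to 120756694, plus strand), rose from 18.8 ± 1.41 to 70.8 ± 6.75 CPM (log2 1.91 ± 0.10, adjusted p = 2.42e-10). Transcripts of the growth factor gene Hgf fell by 2.26 ± 0.18 on the log2 scale, from 278 ± 1.19 to 58.04 ± 16.9 CPM (adjusted p = 4.29e-08). Hlf, a stem cell transcription factor (ENSMUSG00000003949.13, chromosome 11, 90336536 to 90390895, minus strand), fell by 1.80 ± 0.12 (adjusted p = 5.67e-09).

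Among the other largest increases at 4 h were Pald1 (3.42 ± 0.24), Lgals3 (3.03 ± 0.21), which encodes galectin-3, and Bmf (2.57 ± 0.23), a pro-apoptotic BCL2 family gene. The interferon-induced antiviral gene Rsad2 (log2 2.79 ± 0.57, adjusted p = 0.00225) was called on all libraries, but its change was 1.82 and not called (adjusted p = 0.0696) without 4 h library B. Among the largest decreases were Gda (-1.90 ± 0.15), which encodes guanine deaminase, the peptide hormone receptor gene Calcrl (-1.89 ± 0.19) and the activation antigen gene Cd69 (-1.78 ± 0.16). So were Far2 (-1.86 ± 0.26), the transporter gene Slc22a4 (-1.72 ± 0.16) and the acyl-CoA thioesterase gene Acot1 (-1.68 ± 0.11). Myb, a factor of immature haematopoietic cells, fell by 1.18 ± 0.14 (adjusted p = 7.82e-06), from 976 ± 1.56 to 432 ± 65.4 CPM, and Kit, the stem cell factor receptor, by 0.52 ± 0.11 (adjusted p = 0.00366). Hoxa9 transcripts, which sum any reads from the endogenous gene and from the fusion (ENSMUSG00000038227.12, chromosome 6, 52223100 to 52231089, minus strand), rose from 140.4 ± 13.9 to 213 ± 26.4 CPM (log2 0.60 ± 0.10, adjusted p = 4.65e-04). Its neighbours on that chromosome, Hoxa7 and Hoxa10, had no read in any library. Reads counted for Esr1 may likewise come in part from the fusion. Esr1, the oestrogen receptor gene (ENSMUSG00000019768.13, chromosome 10, 4611593 to 5005614, plus strand), stood at 44.5 ± 2.64 and 59.6 ± 2.43 CPM (log2 0.42 ± 0.094, adjusted p = 0.00452), a call lost without 4 h library A (adjusted p = 0.054) or 0 h library B (adjusted p = 0.0837). The granule and neutrophil genes of the later course, among them Ltf, Ngp, Camp, S100a8 and S100a9, lay at or under 1.09 CPM at 0 h and 1.01 CPM at 4 h and were not called.

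By gene group, the cholesterol synthesis genes fell at 4 h: of 24 measured, 1 rose, 13 fell and 10 were not called (2 higher and 15 lower when adjusted over the list alone), with Hsd17b7 and Msmo1 among the lower ones. The camera test of that list against all other genes gave adjusted p = 2.46e-11. With an estimated correlation it gave 0.0386. Of 7 measured oestrogen receptor targets, 5 rose, 0 fell and 2 were not called. The counts adjusted over the list alone did not differ, and the list was called upward. The oestrogen target list had adjusted p = 1.68e-04, and adjusted p = 0.0386 with an estimated correlation. Its members include Rara (1.64 ± 0.26) and Xbp1 (0.61 ± 0.086), together with Esr1 itself, and most are known as genes that estradiol induces in other cells. These 2 lists were the ones whose call held with an estimated correlation at 4 h. With the preset correlation 12 of 35 lists were called, 6 up and 6 down, and the self-contained test fry called 9. Of 28 myeloid transcription factor genes, 12 rose, 1 fell and 15 were not called (13 higher and 2 lower when adjusted over the list alone), including Id2 (2.10 ± 0.22). The myeloid transcription factor list had adjusted p = 1.89e-05, and adjusted p = 0.602 with an estimated correlation. Of 21 glycolysis genes, 10 rose, 3 fell and 8 were not called (11 higher and 4 lower when adjusted over the list alone), including Aldoc (4.34 ± 0.28), Pgk1 (0.90 ± 0.10) and Pkm (0.79 ± 0.12). The glycolysis list had adjusted p = 0.01, and adjusted p = 0.718 with an estimated correlation. Of 22 immediate early genes, 7 rose, 2 fell and 13 were not called (8 higher and 2 lower when adjusted over the list alone), including Fos (1.28 ± 0.27) and Dusp5 (1.19 ± 0.16). The immediate early list had adjusted p = 0.0111, and adjusted p = 0.718 with an estimated correlation. Of 22 stem and progenitor genes, 5 rose, 10 fell and 7 were not called (6 higher and 11 lower when adjusted over the list alone), with Angpt1 (-1.35 ± 0.17) and Ikzf2 (-1.20 ± 0.16) among the lower ones. The stem and progenitor list had adjusted p = 0.0463, and adjusted p = 0.718 with an estimated correlation.

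Markers of other cell types and signs of RNA quality also moved at 4 h. Of 12 B cell genes, 4 rose, 1 fell and 7 were not called (6 higher and 2 lower when adjusted over the list alone), with Dntt (1.49 ± 0.15) and Ighm (1.43 ± 0.23) higher and Rag1 (-1.17 ± 0.22) lower. The B cell list had adjusted p = 0.0463, and adjusted p = 0.718 with an estimated correlation. The mitochondrially encoded transcripts were called upward as a list, with 1 of 12 called singly and 6 when adjusted over the list alone. The mitochondrial list had adjusted p = 0.0111, and adjusted p = 0.718 with an estimated correlation. Lists called downward with few single calls were S phase (4 of 28 lower) and ribosome biogenesis (1 of 26 lower, 0 when adjusted over the list alone). The S phase list had adjusted p = 0.0111, and adjusted p = 0.743 with an estimated correlation. The ribosome biogenesis list had adjusted p = 0.01, and adjusted p = 0.743 with an estimated correlation. So were purine synthesis (1 of 15 lower) and primary granule genes (2 of 14 lower). The purine list had adjusted p = 0.0427, and adjusted p = 0.718 with an estimated correlation. The primary granule list had adjusted p = 0.0463, and adjusted p = 0.718 with an estimated correlation. Median, mean and camera direction differed in sign at 4 h for the surface receptors (median -0.04, mean 0.17, downward), the ATF4 targets (-0.07, 0.28, downward), the p53 targets (0.00, 0.17, downward), the monocyte genes (0.00, 0.09, downward), the megakaryocyte genes (0.00, 0.17, upward) and the mast cell genes (-0.18, 0.07, downward), none of them called.

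At 24 h a number of granulocyte transcripts were higher than at 0 h and a number of progenitor transcripts lower. Cebpe, the factor of late granulocyte maturation (ENSMUSG00000052435.6, chromosome 14, 54710360 to 54712174, minus strand), rose by 3.75 ± 0.16 on the log2 scale, from 8.96 ± 0.761 to 122 ± 3.44 CPM (adjusted p = 3.55e-13). Prg2, which encodes the eosinophil major basic protein (ENSMUSG00000027073.5, chromosome 2, 84980461 to 84983632, plus strand), rose by 5.00 ± 0.16, from 4.28 ± 0.794 to 139 ± 5.51 CPM (adjusted p = 7.63e-15). Tgm2, tissue transglutaminase (ENSMUSG00000037820.12, chromosome 2, 158116402 to 158146436, minus strand), rose by 7.74 ± 0.25, from 1.304 ± 0.235 to 283 ± 0.616 CPM (adjusted p = 7.63e-15). Mpo, the myeloperoxidase gene (ENSMUSG00000009350.10, chromosome 11, 87793581 to 87804413, plus strand), rose from 3852 ± 186 to 10345 ± 391 CPM (log2 1.42 ± 0.23, adjusted p = 7.17e-05). Flt3, a receptor kinase of progenitors (ENSMUSG00000042817.14, chromosome 5, 147330741 to 147400489, minus strand), fell by 5.49 ± 0.20, from 315 ± 31.9 to 7.01 ± 1.23 CPM (adjusted p = 3.85e-14). Cd34, a progenitor surface marker (ENSMUSG00000016494.6, chromosome 1, 194938819 to 194961279, plus strand), fell by 1.69 ± 0.094, from 2765 ± 64.7 to 860.2 ± 22.1 CPM (adjusted p = 2.12e-11).

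The largest increases at 24 h also took in Prg3, a homologue of Prg2 (5.04 ± 1.16 to 429 ± 6.15 CPM), Adgre4 (6.29 ± 0.57), Tmc7 (5.92 ± 0.52), the glutathione transferase gene Mgst1 (5.31 ± 0.24), the glucocorticoid-activating enzyme gene Hsd11b1 (5.22 ± 0.21) and the C-type lectin gene Clec4a2 (4.98 ± 0.29). The largest decreases took in Mmp12 (-6.94 ± 0.79), which encodes macrophage elastase, Myh7b (-6.01 ± 0.19), the protease gene Lgmn (-5.49 ± 0.22), the recombinase gene Rag2 (-5.44 ± 0.18), Aebp1 (-5.27 ± 0.14) and Gas6 (-5.21 ± 0.17), a ligand of TAM receptors. The chemokine gene Ccl2 stood at 0.366 ± 0.05501 CPM at 0 h and had no read in either 24 h library (adjusted p = 0.00277). Elane, neutrophil elastase, rose from 2.81 ± 0.105 to 18.4 ± 2.47 CPM (log2 2.71 ± 0.26, adjusted p = 7.25e-08). Itgam, the integrin CD11b (ENSMUSG00000030786.15, chromosome 7, 128062640 to 128118491, plus strand), rose from 4.64 ± 0.261 to 31.5 ± 0.508 CPM (log2 2.75 ± 0.16, adjusted p = 4.56e-11). Not called at 24 h were Ltf (adjusted p = 0.768), Ngp (0.0981), Camp (0.577), S100a8 (0.442), S100a9 (0.87) and Cybb (0.898). Ngp was called by DESeq2 (adjusted p = 0.0163) and without a filter on low counts (adjusted p = 6.43e-06). Kit fell by 0.95 ± 0.11 (adjusted p = 1.77e-06) and Meis1, a partner of HOX proteins, by 1.49 ± 0.13 (adjusted p = 1.14e-08). Myb (log2 -0.17 ± 0.14), Myc (-0.26 ± 0.11) and Mki67 (-0.07 ± 0.13), the gene of the Ki-67 proliferation antigen, were not called at 24 h. Myc was called without 72 h library A (adjusted p = 0.0428) or B (adjusted p = 0.0427) and by DESeq2 (adjusted p = 0.0486). Irf8 was back at 18.6 ± 0.9802 CPM (log2 -0.02 ± 0.10, adjusted p = 0.917). Hoxa9 stood at 181 ± 0.0529 CPM (log2 0.36 ± 0.10, adjusted p = 0.0123). That call was lost without single libraries, with adjusted p = 0.0594 without 24 h library A, 0.0535 without 24 h library B and 0.143 without 0 h library B.

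Among the gene groups at 24 h, 14 of 35 lists were called, 11 up and 3 down, and 2 held with an estimated correlation. One was the eosinophil list, of whose 10 measured genes 8 rose, 0 fell and 2 were not called (9 higher and 0 lower when adjusted over the list alone). The eosinophil list had adjusted p = 1.69e-07, and adjusted p = 0.0361 with an estimated correlation. The median log2 change of that list was 3.78, or 2.54 with genes that had a group without reads at their bound. Epx, eosinophil peroxidase, had no read at 0 h and 0.781 ± 0.196 CPM at 24 h, and Ear2, an eosinophil ribonuclease gene, rose by 3.81 ± 0.77. The other was the mast cell and basophil list, of whose 7 measured genes 4 rose, 0 fell and 3 were not called (5 higher and 0 lower when adjusted over the list alone), with Hdc (3.69 ± 0.14), histidine decarboxylase, Il1rl1 (3.43 ± 0.36) and Cpa3 (1.85 ± 0.15). The mast cell and basophil list had adjusted p = 3.53e-05, and adjusted p = 0.0361 with an estimated correlation. Of 14 primary granule genes, 9 rose, 0 fell and 5 were not called, including Ms4a3 (2.77 ± 0.21). The primary granule list had adjusted p = 2.39e-06, and 0.136 with an estimated correlation. Of 18 secondary granule genes, 8 rose, 1 fell and 9 were not called, with Ltb4r1 (4.66 ± 0.17) and Fcnb (3.52 ± 0.25) higher and Mmp8 (-2.59 ± 0.29) lower. The secondary granule list had adjusted p = 3.81e-04, and adjusted p = 0.474 with an estimated correlation. Of 23 mature neutrophil genes, 8 rose, 2 fell and 13 were not called, including Cxcr2 (2.46 ± 0.24). The mature neutrophil list had adjusted p = 0.0162, and adjusted p = 0.582 with an estimated correlation. Of 20 surface receptor genes, 13 rose, 3 fell and 4 were not called, including Ccr1 (3.79 ± 0.20) and Fcgr4 (3.47 ± 0.32). The surface receptor list had adjusted p = 1.53e-05, and adjusted p = 0.33 with an estimated correlation. Of 16 unfolded protein response genes, 12 rose, 0 fell and 4 were not called (13 higher and 0 lower when adjusted over the list alone), including Xbp1 (1.24 ± 0.086), Calr (1.06 ± 0.11) and Dnajb9 (0.87 ± 0.14). The unfolded protein response list had adjusted p = 1.40e-06, and adjusted p = 0.33 with an estimated correlation.

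Of 24 cholesterol synthesis genes, 10 rose, 1 fell and 13 were not called (12 higher and 2 lower when adjusted over the list alone) at 24 h, with Fdps (1.23 ± 0.16) and Mvd (0.92 ± 0.16) among the higher ones. The cholesterol synthesis list had adjusted p = 0.0162, and adjusted p = 0.474 with an estimated correlation. The myeloid transcription factors were called upward with 11 higher and 5 lower genes of 28. The myeloid transcription factor list had adjusted p = 0.0275, and adjusted p = 0.528 with an estimated correlation. Egr1 (-4.61 ± 0.77) and Klf4 (-3.25 ± 0.51) were among the lower ones. The NADPH oxidase list was called upward with 4 of 8 higher. The NADPH oxidase list had adjusted p = 0.0302, and adjusted p = 0.494 with an estimated correlation. The lists called downward were stem and progenitor genes, of which 4 rose, 13 fell and 5 were not called (7 higher and 13 lower when adjusted over the list alone), and immediate early genes, of which 1 rose, 8 fell and 13 were not called. The stem and progenitor list had adjusted p = 9.36e-04, and adjusted p = 0.306 with an estimated correlation. The immediate early list had adjusted p = 0.0147, and adjusted p = 0.518 with an estimated correlation. The other one was B cell genes, of which 1 rose, 10 fell and 1 was not called. The B cell list had adjusted p = 8.60e-06, and adjusted p = 0.0544 with an estimated correlation. The B cell genes included Ebf1 (-5.15 ± 0.12) and Dntt (-5.78 ± 0.28), and the immediate early genes Spry4 (-3.65 ± 0.13) and Dusp6 (-2.56 ± 0.19), feedback regulators of receptor kinase signalling. The mitochondrially encoded transcripts rose beside these groups, with 9 of 12 higher, for example mt-Nd2 (0.83 ± 0.16). The mitochondrial list had adjusted p = 5.69e-04, and adjusted p = 0.45 with an estimated correlation. S phase (1 higher and 2 lower of 28, and 0 and 1 when adjusted over the list alone) and G2/M genes (1 higher of 28, and 0 when adjusted over the list alone) were not called as lists (adjusted p = 0.464 and 0.986). Median, mean and camera direction differed in sign for the monocyte genes (0.14, -0.18, upward), the pyrimidine genes (0.02, -0.10, upward) and the apoptosis regulators (0.04, 0.35, downward), none of them called.

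At 120 h the libraries held abundant transcripts of neutrophils and macrophages that were near the detection limit at 0 h. Ltf, which encodes lactoferrin of the secondary granules (ENSMUSG00000032496.4, chromosome 9, 111019271 to 111042767, plus strand), rose from 0.737 ± 0.0309 to 5014 ± 1020.5 CPM (log2 12.71 ± 0.38, adjusted p = 7.27e-17). The calprotectin genes S100a8 (ENSMUSG00000056054.9, chromosome 3, 90668978 to 90670035, plus strand) and S100a9 rose from 0.865 ± 0.365 to 4092 ± 609 and from 1.09 ± 0.331 to 5743 ± 1106 CPM (log2 12.15 ± 0.36 and 12.31 ± 0.32). Cybb, the catalytic subunit of the phagocyte oxidase (ENSMUSG00000015340.7, chromosome X, 9435252 to 9487771, minus strand), rose from 0.376 ± 0.103 to 2677 ± 324 CPM (log2 12.74 ± 0.34, adjusted p = 1.46e-17). Mpo fell by 5.64 ± 0.28 on the log2 scale to 78.5 ± 22.4 CPM (adjusted p = 1.21e-13). Cd34 fell by 5.98 ± 0.11 to 44.3 ± 0.267 CPM (adjusted p = 4.91e-19) and Mki67 by 3.03 ± 0.14 to 70.4 ± 19.1 CPM (adjusted p = 3.51e-14).

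The largest increases at 120 h took in Rin2, a Ras and Rab interactor, and Ceacam10, a secretory glycoprotein gene, neither of which had a read at 0 h. They reached 227 ± 21.97 and 63.6 ± 21.1 CPM, at least 6707-fold and 1876-fold higher than 3 counts over both 0 h libraries allow. The others were Bst1 (14.08 ± 0.46), Clec4a1 (14.01 ± 0.36), the inhibitory receptor gene Pilra (13.98 ± 0.49), Ms4a4c (13.92 ± 0.39), and Gpnmb (13.72 ± 0.23), a glycoprotein of macrophages. The lysozyme gene Lyz1 (ENSMUSG00000069515.5, chromosome 10, 117287797 to 117292868, minus strand) rose from 0.185 ± 0.0598 to 2511 ± 60.8 CPM (log2 13.72 ± 0.29). Lyz2, the other lysozyme gene (ENSMUSG00000069516.7, chromosome 10, 117277331 to 117282321, minus strand), had no read at 0 h and 0.539 ± 0.177 CPM at 120 h; DESeq2 did not call it (adjusted p = 0.322). The largest decreases were Aebp1 (-11.49 ± 0.24), Myh7b (-11.14 ± 0.33), Rag2 (-10.93 ± 0.29), the cation transporter gene Slc22a3 (-10.72 ± 0.21), and Hmgcll1 (-10.46 ± 0.37). They also took in the signalling inhibitor gene Spry4 (-9.97 ± 0.24), the surrogate light chain gene Igll1 (-9.92 ± 0.22) and the troponin gene Tnnt2 (-9.78 ± 0.33). Kit fell by 4.48 ± 0.13, Myb by 5.01 ± 0.17, Myc by 4.26 ± 0.12, Meis1 by 2.21 ± 0.14 and Dhodh, an enzyme of pyrimidine synthesis, by 2.56 ± 0.11. Itgam (log2 9.02 ± 0.20), Csf3r, the G-CSF receptor (3.98 ± 0.15), Irf8 (2.63 ± 0.10), Cebpe (3.55 ± 0.16), Ngp (12.23 ± 0.39) and Camp (11.90 ± 0.39) rose, whereas Elane was not called (0.41 ± 0.30, adjusted p = 0.217). Hoxa9 stood at 302 ± 34.4 CPM and Esr1 at 88.5 ± 7.51 CPM, 1.09 ± 0.11 and 0.98 ± 0.095 above 0 h on the log2 scale (adjusted p = 6.83e-09 and 7.37e-09). Changes at 96 and 120 h are relative to the scaling, since by library size alone the median gene lay at -0.349 and -0.469 relative to 0 h, against 0.105 to 0.125 in R07 at 36 to 120 h.

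Most lists of myeloid maturation moved mainly upward at 120 h, and the primary granule genes did not. All 18 secondary granule genes rose, including Olfm4 (12.47 ± 0.37). The secondary granule list had adjusted p = 2.54e-09, and adjusted p = 0.175 with an estimated correlation. All 23 mature neutrophil genes rose, including Retnlg (13.36 ± 0.41) and Fpr2 (12.76 ± 0.45). The mature neutrophil list had adjusted p = 5.64e-10, and adjusted p = 0.175 with an estimated correlation. The median there was 9.80, or 9.39 with the gene without reads at 0 h at its bound. Of 25 monocyte and macrophage genes, 23 rose, 1 fell and 1 was not called, with the complement genes C1qc (13.64 ± 0.35) and C1qb (13.05 ± 0.34) and the M-CSF receptor gene Csf1r (11.49 ± 0.33) among the higher ones. The monocyte and macrophage list had adjusted p = 7.53e-10, and adjusted p = 0.175 with an estimated correlation. All 8 NADPH oxidase genes rose, including Cyba (3.66 ± 0.18) and Ncf1 (3.40 ± 0.12). The NADPH oxidase list had adjusted p = 3.61e-04, and adjusted p = 0.192 with an estimated correlation. All 20 surface receptor genes rose, including C5ar1 (12.28 ± 0.37) and Tlr13 (13.01 ± 0.29). The surface receptor list had adjusted p = 5.64e-10, and adjusted p = 0.175 with an estimated correlation. Of 28 myeloid transcription factors, 25 rose, 2 fell and 1 was not called, including Maf (9.81 ± 0.26) and Klf2 (7.94 ± 0.31). The myeloid transcription factor list had adjusted p = 5.60e-07, and adjusted p = 0.175 with an estimated correlation. All 25 interferon response genes rose, including Ifit3 (12.78 ± 0.38), Oasl2 (11.75 ± 0.35) and Isg15 (11.55 ± 0.42). The interferon response list had adjusted p = 5.23e-10, and adjusted p = 0.175 with an estimated correlation. Of 22 NF-kB and inflammatory genes, 21 rose, 1 fell and 0 were not called, including Il1b (9.80 ± 0.59). The NF-kB list had adjusted p = 5.60e-07, and adjusted p = 0.245 with an estimated correlation. Of 22 immediate early genes, 17 rose, 4 fell and 1 was not called. The immediate early list had adjusted p = 0.00332, and adjusted p = 0.334 with an estimated correlation. Of 17 apoptosis regulators, 13 rose, 2 fell and 2 were not called, including Bmf (7.28 ± 0.20). The apoptosis list had adjusted p = 0.00332, and adjusted p = 0.181 with an estimated correlation. Of 21 p53 targets, 14 rose, 3 fell and 4 were not called (15 higher and 3 lower when adjusted over the list alone). The p53 target list had adjusted p = 0.0276, and adjusted p = 0.248 with an estimated correlation.

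Growth-related groups fell at 120 h. All 28 G2/M genes fell, including Ccnb1 (-3.94 ± 0.14) and Ttk (-3.76 ± 0.13). The G2/M list had adjusted p = 1.54e-10, and adjusted p = 0.248 with an estimated correlation. Of 28 S phase genes, 1 rose, 27 fell and 0 were not called, including Orc1 (-5.48 ± 0.19) and Rrm2 (-4.42 ± 0.14). The S phase list had adjusted p = 5.23e-10, and adjusted p = 0.217 with an estimated correlation. All 26 ribosome biogenesis genes fell, including Dkc1 (-4.37 ± 0.15) and Nolc1 (-3.45 ± 0.12). The ribosome biogenesis list had adjusted p = 2.08e-09, and adjusted p = 0.197 with an estimated correlation. Of 21 pyrimidine synthesis and salvage genes, 5 rose, 14 fell and 2 were not called, with Ctps (-4.73 ± 0.16) lower and Cmpk2 (5.91 ± 0.24), which is also interferon-induced, higher. The pyrimidine list had adjusted p = 0.0361, and adjusted p = 0.197 with an estimated correlation. Of 15 purine synthesis genes, 2 rose, 13 fell and 0 were not called, including Ppat (-3.76 ± 0.14). The purine list had adjusted p = 4.70e-04, and adjusted p = 0.192 with an estimated correlation. Of 27 oxidative phosphorylation genes, 1 rose, 23 fell and 3 were not called, including Atp5b (-1.62 ± 0.093). The oxidative phosphorylation list had adjusted p = 4.86e-04, and adjusted p = 0.424 with an estimated correlation. Of 22 stem and progenitor genes, 5 rose, 17 fell and 0 were not called, with Sox4 (-8.78 ± 0.25) and Angpt1 (-7.41 ± 0.24) lower and Tgm2 (8.95 ± 0.26) higher. The stem and progenitor list had adjusted p = 4.70e-04, and adjusted p = 0.175 with an estimated correlation. In all, 20 of 35 lists were called at 120 h, 13 up and 7 down, none of them with an estimated correlation (lowest adjusted p = 0.175) and 31 by fry. The counts adjusted over the list alone differed from those over all genes for the p53 targets and the mitochondrial transcripts.

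Other lists at 120 h held members that went both ways and were not called. Of 14 primary granule genes, 2 rose, 8 fell and 4 were not called (adjusted p = 0.103). Ctsg (-5.34 ± 0.21) and Nkg7 (-6.30 ± 0.44) were lower and Hp (6.20 ± 0.19), on both granule lists, was higher. Of 9 genes of MYC and its partners, 5 rose, 3 fell and 1 was not called (adjusted p = 0.649; median 0.70, mean -0.78, test upward), with the MYC antagonist Mxd1 (3.44 ± 0.14) higher and Mycn lower, from 1.595 ± 0.0323 CPM to no read at 120 h. Of 15 G1 cyclin and CDK inhibitor genes, 9 rose, 6 fell and 0 were not called (adjusted p = 0.577; median 0.35, a direction that turns with library size alone), with Ccnd1 (2.82 ± 0.43) higher and Cdk4 (-2.42 ± 0.11) lower. Of 24 cholesterol genes, 7 rose, 11 fell and 6 were not called (adjusted p = 0.577). Of 22 ATF4 targets, 8 rose, 12 fell and 2 were not called (adjusted p = 0.22), with Psat1 (-4.59 ± 0.13), a serine synthesis enzyme, lower. Of 16 unfolded protein response genes, 5 rose, 9 fell and 2 were not called (adjusted p = 0.714). Of 7 oestrogen receptor targets, 5 rose, 2 fell and 0 were not called (adjusted p = 0.209), with Ctsd (4.72 ± 0.15) higher and Igfbp4 (-3.93 ± 0.14) lower. Of 21 glycolysis genes, 10 rose, 9 fell and 2 were not called (adjusted p = 0.78; median -0.01, mean 0.54, test upward).

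Among markers of other cell types at 120 h, of 13 dendritic cell genes, 9 rose, 2 fell and 2 were not called (median 5.27, or 4.57 with bounds), led by Cd74 (12.95 ± 0.50), the invariant chain gene, which macrophages also express. The dendritic cell list had adjusted p = 0.0262, and adjusted p = 0.248 with an estimated correlation. All 10 eosinophil genes were higher than at 0 h (median 3.40, or 2.67 with bounds). The eosinophil list had adjusted p = 0.00241, and adjusted p = 0.175 with an estimated correlation. Of 6 erythroid genes, 0 rose, 3 fell and 3 were not called (adjusted p = 0.24). Of 7 mast cell and basophil genes, 2 rose, 4 fell and 1 was not called (adjusted p = 0.264), with Mcpt8 (-7.70 ± 0.21) lower. Of 9 megakaryocyte genes, 5 rose, 4 fell and 0 were not called (adjusted p = 0.649). Of 6 T and NK cell genes, 4 rose, 1 fell and 1 was not called (adjusted p = 0.312). Of 12 B cell genes, 4 rose, 7 fell and 1 was not called (adjusted p = 0.417), with Ebf1 (-9.44 ± 0.18) lower. Of 12 mitochondrially encoded transcripts, 3 rose, 0 fell and 9 were not called (1 higher and 0 lower when adjusted over the list alone); the list was not called (adjusted p = 0.717), and its direction turns with library size alone. Of 5 haemoglobin and RNA quality genes, 3 rose, 1 fell and 1 was not called (adjusted p = 0.209), with the nuclear RNAs Neat1 (3.88 ± 0.24) and Malat1 (2.93 ± 0.22) higher. The share of reads outside annotated genes was 4.06 ± 0.081% at 0 h, 6.39 ± 0.12% at 96 h and 5.82 ± 0.14% at 120 h, so it was higher beside the myeloid groups.

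The times between followed gene-specific courses. Mpo peaked at 10673 ± 618 CPM at 36 h before its fall, and Elane at 100.01 ± 11.01 CPM at 72 h. Prg2 reached 1489 ± 251 CPM at 48 h and 1401 ± 104 CPM at 72 h and was at 41.7 ± 2.75 CPM at 120 h. Fcnb, a ficolin of granulocyte precursors, reached 899 ± 64.98 CPM at 96 h and stood at 201 ± 11.4 CPM at 120 h. S100a8 went from 21.4 ± 9.23 CPM at 48 h to 1338 ± 253 CPM at 72 h and 6242 ± 1407 CPM at 96 h, and Ltf from 2.095 ± 0.389 to 266 ± 136 and 6237 ± 547 CPM. Lyz1 went from 54.5 ± 6.69 CPM at 72 h to 517 ± 162 CPM at 96 h and 2511 ± 60.8 CPM at 120 h. Gfi1b peaked at 41.8 ± 5.47 CPM at 8 h, and Irf8 went from 70.8 ± 6.75 CPM at 4 h to 17.6 ± 1.24 CPM at 36 h and 118 ± 1.38 CPM at 120 h. Mki67 held between 453 ± 53.7 CPM at 12 h and 807 ± 6.52 CPM at 72 h and then dropped to 70.4 ± 19.1 CPM. Hoxa9 rose to 616 ± 1.47 CPM and Esr1 to 164 ± 5.19 CPM at 96 h.

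**Figure D3:**
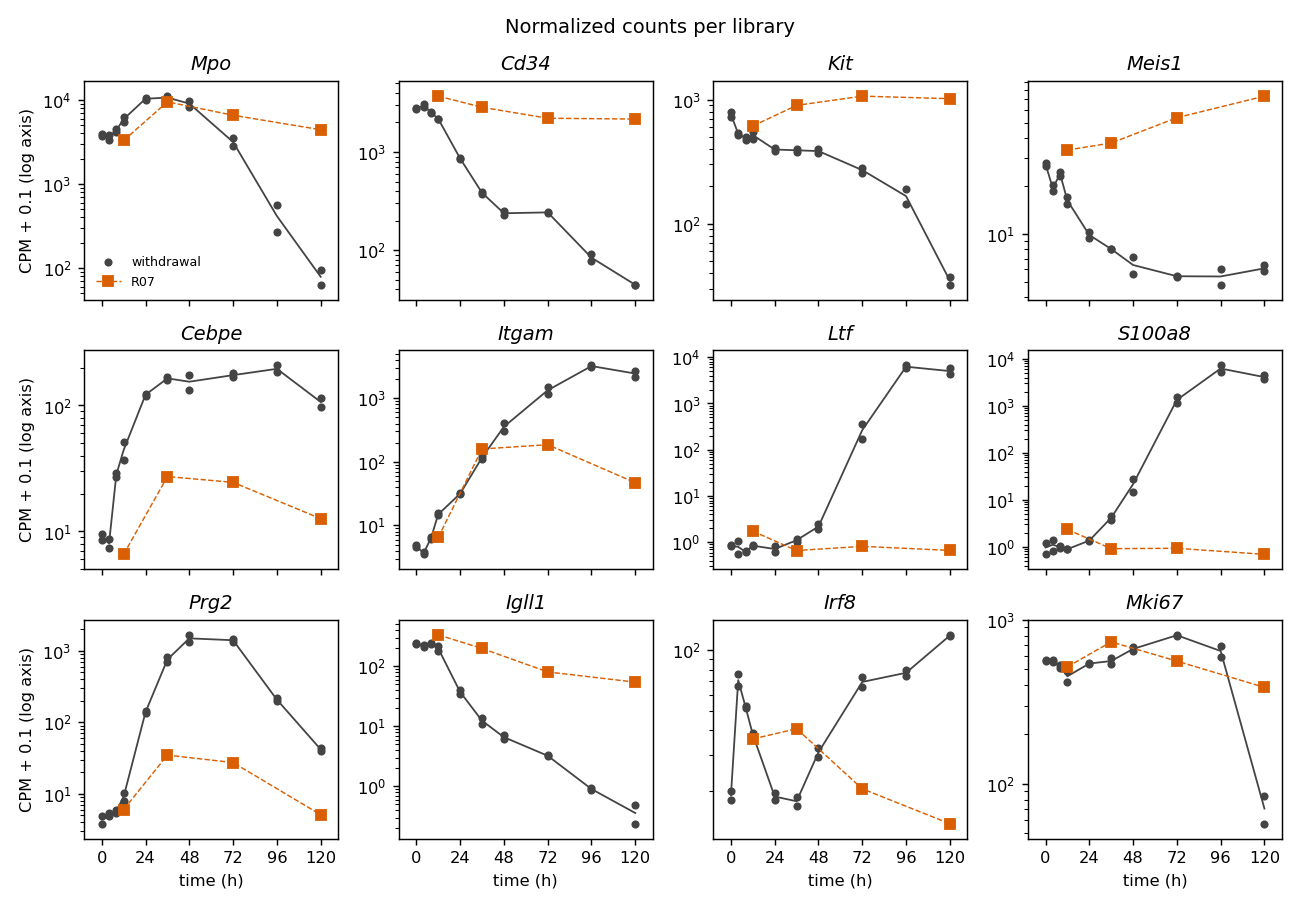
CPM of single genes (vertical axis, log scale) against hours after withdrawal (horizontal axis). Grey points are withdrawal libraries, joined through their means, and orange squares are single R07 libraries; Itgam, for example, went from 4.64 to 2440.0 CPM in withdrawal and stood at 46.8 CPM in R07 at 120 h.

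The comparison of R07 with withdrawal at the same 4 times asks how the treated cells differed from cells that differentiate. Progenitor and B-lymphoid transcripts were among those higher in R07 than in withdrawal. Rag2 (ENSMUSG00000032864.4, chromosome 2, 101624718 to 101632529, plus strand) stood at 207, 153, 114 and 93.4 CPM at 12, 36, 72 and 120 h, against 11.1 ± 0.0876, 1.701 ± 0.314, 0.0603 ± 0.0164 and 0.0553 ± 0.0783 CPM in withdrawal (log2 8.09 ± 1.00, adjusted p = 0.00185). Flt3 was higher by 6.37 ± 0.54 (adjusted p = 4.78e-04), with 561, 447, 920.2 and 952 CPM. Cd34 was higher by 3.40 ± 0.60 (adjusted p = 0.00732), with 3707, 2855, 2208 and 2165 CPM. Meis1 (ENSMUSG00000020160.15, chromosome 11, 18879817 to 19018985, minus strand) was higher by 2.68 ± 0.34 (adjusted p = 0.00202), with 33.5, 37.1, 53.5 and 73.1 CPM against 5.98 ± 0.363 CPM in withdrawal at 120 h. Cebpe was lower (log2 -2.81 ± 0.15, adjusted p = 8.89e-05), with 6.49, 27.2, 24.4 and 12.5 CPM. Hoxa9 was lower (-1.14 ± 0.16, adjusted p = 0.00302), with 79.9, 65.9, 203 and 178 CPM, and so was Esr1 (-0.81 ± 0.11, adjusted p = 0.00221), with 28.4, 38.7, 74.1 and 54.7 CPM. In all, 2262 of 13641 genes were called, 1431 higher and 831 lower in R07.

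The largest positive differences were Depp1 (9.85 ± 0.56), the recombinase gene Rag1 (9.42 ± 0.61), Inhbb (9.24 ± 0.89), an inhibin and activin subunit, and Gpr12 (8.17 ± 0.67). They also took in Aebp1 (7.87 ± 1.20), the B-lymphoid factor gene Ebf1 (7.79 ± 1.07) and Trib2 (7.37 ± 1.10), a pseudokinase gene. The largest negative ones were Trem2, a macrophage receptor gene with no read in any R07 library and 144 ± 25.6 CPM in withdrawal at 120 h, March1 (-9.25 ± 1.12), Ear2 (-8.62 ± 1.03) and Mgst1 (-5.31 ± 0.93). The others were the complement receptor gene C3ar1 (-9.49 ± 1.97), Mcemp1 (-4.15 ± 1.22), Fcnb (-4.06 ± 1.07) and the dipeptidase gene Dpep2 (-4.01 ± 0.92). Without the R07 library at 72 h C3ar1 (adjusted p = 0.0802), Dpep2 (0.0861), Mcemp1 (0.171) and Fcnb (0.0814) were no longer called. Mcemp1 lost its call with each of 9 of the 12 libraries left out and Fcnb with each of 7. Kit was higher by 2.30 ± 0.64 (adjusted p = 0.0385), a call that ended with each of 9 of the 12 libraries left out, with adjusted p = 0.114 without the R07 library at 72 h. Itgam stood at 6.37, 159, 186 and 46.8 CPM in R07 and at 14.8 ± 0.719, 116 ± 10.8, 1333 ± 254 and 2440.0 ± 377 CPM in withdrawal. The difference was not called (log2 -1.74 ± 0.84, adjusted p = 0.181), but was without the R07 library at 36 h (adjusted p = 0.041) and by DESeq2 (adjusted p = 0.0353). Mpo (1.72 ± 1.09), Myb (1.97 ± 0.84), Mki67 (0.74 ± 0.41) and Dhodh (0.69 ± 0.36) were not called either. All of them, with Itgam and Myc, were called when the spread came from the withdrawal duplicates alone (highest adjusted p = 3.05e-07). Myc (1.97 ± 0.71, adjusted p = 0.088) was called without the R07 library at 12 h (adjusted p = 0.0173), and DESeq2 called Myc (adjusted p = 0.00688) and Myb (adjusted p = 0.0165). S100a8 stood at 2.24, 0.814, 0.8302 and 0.592 CPM and Ltf at 1.64, 0.563, 0.717 and 0.568 CPM in R07. S100a8, S100a9, Ltf, Ngp, Camp and Cybb were not called in this fit, whose spread includes the change of the difference with time. Ngp (adjusted p = 0.0245) and Camp (0.00917) were called without the R07 library at 12 h.

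Single libraries moved the count of R07 against withdrawal by more than 1.5 times. It was 3790 without the R07 library at 12 h and 969 without that at 72 h, and 1417 or 1413 without withdrawal library A or B at 36 h, 1131 or 1130 at 72 h and 1404 or 1277 at 120 h. DESeq2 called 3964 genes, and 9718 were called when the spread came from the withdrawal duplicates alone.

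By gene group, 15 of 35 lists were called for R07 against withdrawal, 4 up and 11 down. None held with an estimated correlation (lowest adjusted p = 0.667), and fry called 12. Of the ways of picking 1 library per time as the R07 arm, 52 of 81 called as many lists. The stem and progenitor genes were higher: of 22, 11 were higher, 2 lower and 9 were not called (13 higher and 2 lower when adjusted over the list alone), including Hlf (5.13 ± 0.54). The stem and progenitor list had adjusted p = 6.51e-04, and adjusted p = 0.734 with an estimated correlation. Of 12 B cell genes, 7 were higher, 1 was lower and 4 were not called (8 higher and 1 lower when adjusted over the list alone), including Dntt (7.03 ± 1.03) and Igll1 (4.66 ± 0.85). The B cell list had adjusted p = 0.0019, and adjusted p = 0.667 with an estimated correlation. The G2/M list was called upward with no gene called singly of 28. The G2/M list had adjusted p = 0.00229, and adjusted p = 0.834 with an estimated correlation. So was the T and NK cell list, with 1 of 5 higher, or 4 when adjusted over the list alone. The T and NK cell list had adjusted p = 0.0426, and adjusted p = 0.667 with an estimated correlation. Of 18 genes on the secondary granule list, 5 were lower, or 7 when adjusted over the list alone, including Ceacam10 (-10.15 ± 1.74) and the receptor gene Ltb4r1 (-3.04 ± 0.29). The secondary granule list had adjusted p = 2.07e-06, and adjusted p = 0.734 with an estimated correlation. Of 23 mature neutrophil genes, 3 were lower, or 4 when adjusted over the list alone, including Trem3 (-1.46 ± 0.18). The mature neutrophil list had adjusted p = 7.17e-06, and adjusted p = 0.734 with an estimated correlation. Of 20 surface receptor genes, 1 was higher, 6 lower and 13 were not called (1 higher and 7 lower when adjusted over the list alone), including Ccr1 (-3.90 ± 0.76). The surface receptor list had adjusted p = 4.58e-04, and adjusted p = 0.804 with an estimated correlation. Of 27 myeloid transcription factors, 5 were lower, including Cebpb (-1.19 ± 0.24) and Id1 (-1.33 ± 0.24). The myeloid transcription factor list had adjusted p = 6.62e-04, and adjusted p = 0.734 with an estimated correlation. Of 9 eosinophil genes, 5 were lower, or 6 with 1 higher when adjusted over the list alone, including Epx (-5.75 ± 0.68). The eosinophil list had adjusted p = 0.00349, and adjusted p = 0.667 with an estimated correlation.

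Of 21 glycolysis genes, 5 were lower in R07, or 7 with 1 higher when adjusted over the list alone, including Hk2 (-1.24 ± 0.16) and the lactate transporter gene Slc16a3 (-1.21 ± 0.21). The glycolysis list had adjusted p = 6.69e-04, and adjusted p = 0.667 with an estimated correlation. Also called downward were the NADPH oxidase genes with 2 of 8 lower, or 4 when adjusted over the list alone. The NADPH oxidase list had adjusted p = 6.69e-04, and adjusted p = 0.734 with an estimated correlation. So were the unfolded protein response genes with 4 of 16 lower, including Xbp1 (-1.16 ± 0.095) and Sdf2l1 (-0.81 ± 0.15). The unfolded protein response list had adjusted p = 0.036, and adjusted p = 0.834 with an estimated correlation. The apoptosis regulators, with 4 lower and 1 higher of 17, including Bcl2a1b (-3.66 ± 0.77), were called downward. The apoptosis list had adjusted p = 0.0213, and adjusted p = 0.804 with an estimated correlation. So were the cholesterol genes, with 2 lower and 1 higher of 24. The cholesterol synthesis list had adjusted p = 0.0114, and adjusted p = 0.834 with an estimated correlation. The monocyte genes, with 0 lower and 1 higher of 20, the chemokine receptor gene Ccr2 (4.18 ± 0.67), completed the 11. The monocyte and macrophage list had adjusted p = 0.00846, and adjusted p = 0.834 with an estimated correlation. Of the 15 lists called, 8 had a median that went against the call at 1 or more of the 4 times, by single R07 libraries. At 12, 36, 72 and 120 h the median of R07 minus withdrawal was 0.00, 1.20, -1.34 and -5.95 for the monocyte genes, 0.58, -0.19, -1.51 and -0.81 for the cholesterol genes and 0.11, 0.11, -0.24 and 2.67 for the G2/M genes. It was 0.69, -1.002, -4.42 and -7.10 for the secondary granule genes, -0.26, 0.03, -2.57 and -5.19 for the surface receptors and -0.39, 0.10, -0.80 and -3.08 for the myeloid transcription factors. It was -0.30, -0.64, 0.13 and 0.03 for the unfolded protein response and 0.50, 0.50, 2.86 and -1.59 for the T and NK cell genes. Median, mean and camera direction differed in sign for the interferon genes (0.52, 0.22, downward), the immediate early genes (0.12, 0.46, downward), the mast cell genes (0.30, 0.51, downward), the p53 targets (0.04, -0.07, downward), oxidative phosphorylation (0.02, 0.03, downward) and the mitochondrial transcripts (0.04, -0.02, downward), none of them called.

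**Figure D4:**
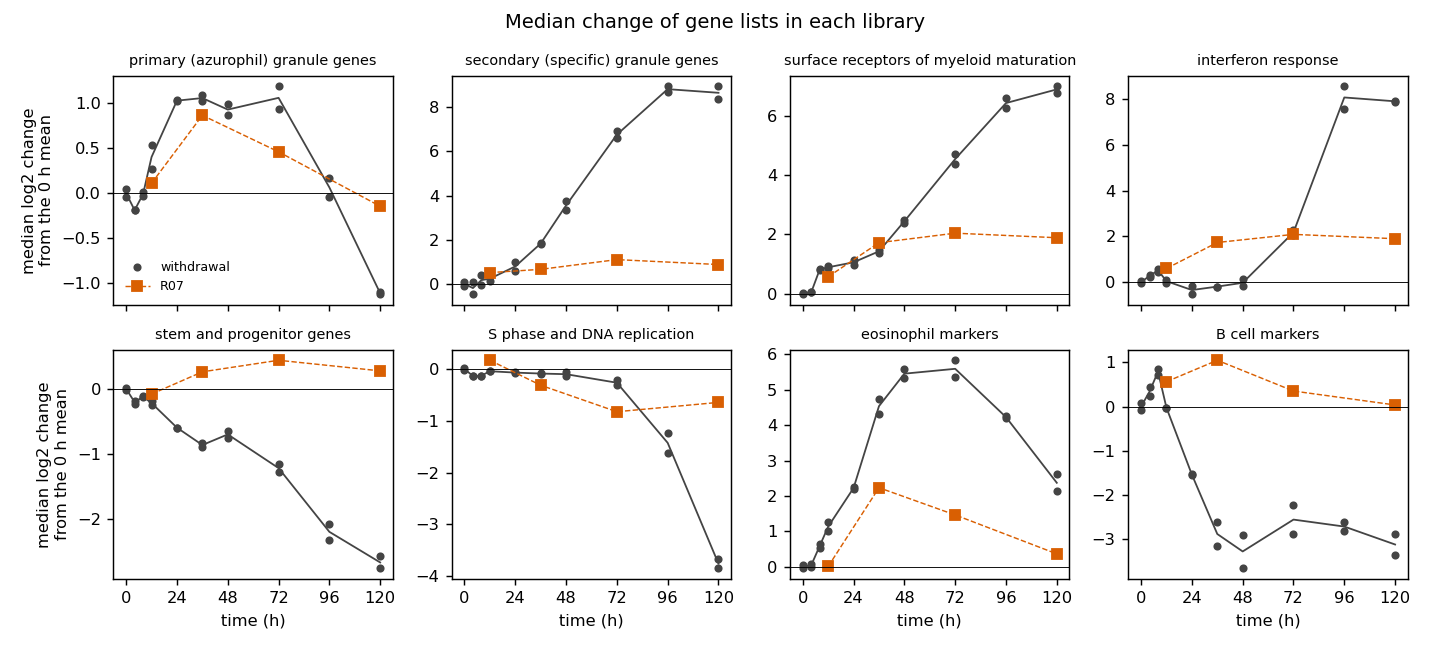
Median log2 change against 0 h of the measured genes of each list (vertical axis) against hours (horizontal axis). Grey points are withdrawal libraries joined through their means, and orange squares are single R07 libraries; the secondary granule genes, for example, lay at 8.96 and 8.36 at 120 h of withdrawal and at 0.88 in R07.

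The comparison of R07 with 0 h asks how the treated cells differed from the starting cells. No library came from cells kept for the same hours without R07 and without withdrawal. R07 and time in culture can thus not be told apart here. The R07 columns also carry a letter that no 0 h column has, and the labels do not give its meaning. No gene was called by edgeR among 13704 tested (lowest adjusted p = 0.138), although 2868 had an unadjusted p under 0.05. DESeq2 called 1326 genes, 996 higher and 330 lower. The test takes the 4 R07 times as replicates, and its count was 2256 (1368 higher, 888 lower) without the R07 library at 12 h. A linear trend over R07 hours called 678 genes, 31 genes were called without a filter on low counts, and 6925 were called when the spread came from the withdrawal duplicates alone, an alternative chosen after seeing the data. All 4 R07 libraries lay beyond both 0 h libraries for 4682 genes, 2450 above and 2232 below, against a chance share of 13.3% of the 13704. The genes named here were chosen by their size after their values were seen, and none was called.

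Tgm2 stood at 1.65, 69.8, 197 and 209 CPM at 12, 36, 72 and 120 h against 1.304 ± 0.235 CPM at 0 h (log2 6.47 ± 1.79, adjusted p = 0.144). Itgam went to 159 CPM at 36 h and 186 CPM at 72 h and was at 46.8 CPM at 120 h, against 4.64 ± 0.261 CPM (log2 4.38 ± 1.28, adjusted p = 0.149). Adgre1, which encodes the macrophage antigen F4/80, stood at 4.77, 22.9, 75.2 and 62.5 CPM against 2.61 ± 0.151 CPM, and Mmp12 at 2.09, 6.89, 100.2 and 129.5 CPM against 1.697 ± 0.175 CPM. Tbxas1, thromboxane synthase (0.564, 12.96, 25.8 and 11.2 CPM), Cd28 (8.12, 37.2, 21.7 and 6.23 CPM), the chemokine gene Ccl3 (6.505, 61.1, 112 and 53.4 CPM) and Olfm1 (4.68, 22.3, 11.4 and 6.86 CPM) also lay above their 0 h levels of 0.3098 ± 0.0626, 0.752 ± 0.0626, 2.54 ± 0.513 and 0.636 ± 0.112 CPM. Below 0 h lay Myh7b (log2 -2.18 ± 0.64), Plekha7 (-1.89 ± 0.82), Rtn4rl2 (-1.85 ± 0.53), the heat shock protein gene Hsph1 (-1.43 ± 0.33), the chromatin protein gene Hmga2 (-1.31 ± 0.31), Etv5 (-1.26 ± 0.39), Tmem132a (-1.25 ± 0.47) and the lipid-binding protein gene Fabp5 (-1.23 ± 0.50). Kit (0.20 ± 0.24), Cd34 (-0.06 ± 0.25), Myb (0.00 ± 0.25), Myc (-0.10 ± 0.21), Hoxa9 (-0.13 ± 0.45) and Esr1 (0.10 ± 0.36) lay within 1 SE of 0 h on average. Without the R07 library at 12 h, Tgm2 (adjusted p = 0.00445), Itgam (0.00976), Adgre1 (0.00889), Mmp12 (0.03), Tbxas1 (0.00514), Cd28 (0.016), Ccl3 (0.0041), Olfm1 (0.00997), Myh7b (0.00388), Rtn4rl2 (0.00999), Hsph1 (0.00569), Hmga2 (0.00388), Etv5 (0.0242) and Fabp5 (0.0153) were called.

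As lists, 17 of 35 were called for R07 against 0 h, 11 up and 6 down, with no member called singly over all genes. None held with an estimated correlation (lowest adjusted p = 0.555) and fry called 0, with a lowest adjusted p of 0.139. The interferon response genes had a median of 1.92, and 18 of 22 were higher when adjusted over the list alone. The interferon response list had adjusted p = 6.58e-11, and adjusted p = 0.555 with an estimated correlation. The ribosome biogenesis genes had a median of -0.68, and 19 of 26 were lower when adjusted over the list alone. The ribosome biogenesis list had adjusted p = 6.58e-11, and adjusted p = 0.555 with an estimated correlation. The surface receptor genes had a median of 1.90, with 11 of 18 higher when adjusted over the list alone. The surface receptor list had adjusted p = 3.11e-07, and adjusted p = 0.555 with an estimated correlation. The NF-kB and inflammatory genes had a median of 0.91, with 10 higher and 1 lower of 18 when adjusted over the list alone. The NF-kB list had adjusted p = 3.02e-04, and adjusted p = 0.555 with an estimated correlation. Called upward too were secondary granule genes (median 1.02), mature neutrophil genes (1.00), monocyte genes (0.90) and myeloid transcription factors (0.64), of which 2, 3, 6 and 6 were higher when adjusted over the list alone. These lists had, in this order, adjusted p = 0.00123, 9.31e-04, 0.0384 and 0.00168. With an estimated correlation it was 0.555, 0.555, 0.588 and 0.555. Of the markers of other cell types, dendritic cell (2.15), eosinophil (2.01), T and NK cell (0.96) and megakaryocyte genes (1.88) were called upward, with 6, 1, 2 and 3 higher when adjusted over the list alone. These lists had, in this order, adjusted p = 0.00123, 0.00527, 0.0384 and 0.0418. With an estimated correlation it was 0.555, 0.555, 0.555 and 0.588. Called downward too were S phase (median -0.41), G2/M (-0.24), purine synthesis (-0.47), oxidative phosphorylation (-0.32) and glycolysis (-0.24), with 0, 0, 6, 0 and 2 lower, and 1 purine gene higher, when adjusted over the list alone. The S phase list had adjusted p = 2.29e-04, and adjusted p = 0.617 with an estimated correlation. The G2/M list had adjusted p = 0.0134, and adjusted p = 0.637 with an estimated correlation. The purine list had adjusted p = 5.21e-04, and adjusted p = 0.555 with an estimated correlation. The oxidative phosphorylation list had adjusted p = 0.00172, and adjusted p = 0.637 with an estimated correlation. The glycolysis list had adjusted p = 0.0384, and adjusted p = 0.555 with an estimated correlation. Of the 17 lists called, 4 had a median that went against the call at 1 time. At 12, 36, 72 and 120 h the median of R07 minus 0 h was 0.17, -0.31, -0.83 and -0.65 for S phase, 0.18, -0.34, -0.54 and -0.32 for oxidative phosphorylation, -0.14, 0.10, -0.22 and -0.57 for G2/M and -0.04, 0.06, -0.17 and -0.36 for glycolysis. The share of reads outside annotated genes was 4.25, 5.37, 5.61 and 4.95% in R07 at 12, 36, 72 and 120 h. Median, mean and camera direction differed in sign for the p53 (0.00, 0.26, downward) and ATF4 targets (0.03, 0.49, downward), neither called.

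Changes within R07 went only partly with those within withdrawal. Across 15371 genes the log2 change from 12 h to 120 h in R07 and that in withdrawal, which share no library, had r = 0.167 (rho = 0.166), with a covariance of 0.377. From 12 h to 72 h r was 0.341 (rho = 0.331) and from 12 h to 36 h 0.156 (rho = 0.0830). Genes are not independent replicates, so no p-value is given. Of 11584 genes called between 12 and 120 h of withdrawal, 6620 (57.1%) moved with the same sign in R07. Measured against the shared 0 h libraries, the changes at 120 h had r = 0.347 and a covariance of 0.767. Unchanged groups simulated with the same shared libraries gave r = 0.400 and a covariance of 0.0381 on average over 100 simulations. The simulated r rests on noise alone, so it cannot be set against the r of 0.347. By covariance, the shared libraries alone gave 0.0381 beside the 0.767 seen.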

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

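The tests of the reporter, of mixed cells and of library size were chosen only after the result was seen; the split tests and the Lyz2 sequence test were not. The 6 anchor genes that differed between the arms at matched times had log2 values of R07 minus withdrawal of -1.14 for Hoxa9, -0.81 for Esr1, 2.30 for Kit, 3.40 for Cd34, 2.68 for Meis1 and -2.81 for Cebpe. These values come from the arm term of the edgeR fit, and Meis1 was the one of them that moved away from 0 h in opposite directions in all libraries of the arms. Kit lost its call with each of 9 of the 12 libraries left out, with adjusted p = 0.114 without the R07 library at 72 h. Of 81 ways of taking 1 library per time as the R07 arm, 1, the real one, called as many genes (2262, against at most 16 for the others). This argues against a random pick of libraries as the source of that count, as far as 81 ways can show. Every other way left R07 libraries in the reference arm, which adds to its spread. The test cannot tell R07 treatment from any other difference between the arms. For the lists 52 of 81 called as many as the real 15 (up to 19). With R07 left in the reference arm, this cannot test chance.

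A signal outside the gene comparisons was the share of reads in no annotated gene, which reached 6.48% in one library; it was 4.06 ± 0.081% at 0 h, 6.39 ± 0.12% at 96 h and 4.25, 5.37, 5.61 and 4.95% in R07. Its source was not tested.

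Lyz2 stayed at or under 0.539 CPM in the group means while Lyz1 reached 2511 ± 60.8 CPM, although mature myeloid cells normally express Lyz2. The line of the table that is not a mouse Ensembl gene went from 0.755 CPM at 0 h to 1422 CPM at 120 h. Reads shared with other genes as the cause are argued against, since 84.6% of 1267 windows of 50 bases of the Lyz2 transcript are absent from all other transcripts, though these windows are shorter than the reads. A reporter transcript in place of Lyz2 may be counted in that line: it rose by 10.85 ± 0.25 on the log2 scale (adjusted p = 2.59e-18), and 0.944% of genes tested rose as much. The labels do not say what the identifier of that line stands for and it was not looked up, so a gene replacement, a second transgene and a deleted Lyz2 stay open.

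In R07, Itgam stood at 159 CPM at 36 h and 186 CPM at 72 h, 34.3-fold or more its 0 h level, and 11 of 18 surface receptor genes were higher than at 0 h when adjusted over the list alone. Library size is argued against, since effective library sizes of R07 and 0 h differ by at most 1.35-fold. Cells like those at 72 to 120 h of withdrawal mixed into R07 are argued against, since the granule and neutrophil lists had a median of at most 0.134 of the level such cells would bring; the bound for it was first set for all source times and applied by source time only after the values were seen. For cells like those at 48 h that median was 0.290, above that bound, and a second test added after that value, over the 5 most risen transcripts, gave 0.0885 with single transcripts at up to 1.04, so such a mixture stays open. An effect of R07 on surface receptors may act apart from granule genes, which was not tested. R07 and time in culture cannot be told apart here, and estradiol in these cultures is not stated.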

How the results depend on the processing

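The fit with all 24 libraries for R07 against 0 h, for genes and lists, and the block on the column letter were chosen only after the result was seen; the other alternatives were set before the data were examined. The count of genes over the course (13174 to 14067) and the counts at 4 to 120 h kept within 1.5 times their values under RLE normalization, no filter on low counts and DESeq2. The counts at 4 to 120 h, for which these were run, did so too with only the 4 libraries compared and with all 24 libraries in the fit. The replicate block set beforehand used the replicate numbers of the labels, which the columns do not carry; in its place a replicate block on the column letter, A or B through all 10 times, was fitted. The labels do not say that a letter marks a shared culture or day, and the differences of A minus B correlated between times by -0.158 to 0.215 (median 0.0138), over 0.1 in 7 of 45 pairs of times, so the letters were not taken as pairs. At 7 of 10 times the libraries correlated best with one of their own letter, a hint the other way from the data. With the replicate block the counts were 13279 over the course, 1832 at 4 h, 3349 at 8 h, 2444 at 12 h, 4182 at 24 h, 6107 at 36 h, 7745 at 48 h, 10179 at 72 h, 11292 at 96 h and 11668 at 120 h, with 20 lists at 120 h. Of the named genes it ended the call of Pola1 at 4 h (adjusted p = 0.0509), gave one to Ngp at 24 h (adjusted p = 0.0229) and turned the sign of Lyz2 at 4 h (-0.0489) and 24 h (-0.0245), where it was not called; it changed no other call.

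For R07 against 0 h edgeR called 0 genes (2868 at an unadjusted p under 0.05), 31 without a filter, 678 with a linear trend over R07 hours, 1326 with DESeq2 and 6925 in the fit of all 24 libraries, whose spread comes from the withdrawal duplicates alone. For R07 against withdrawal the count of 2262 became 3964 with DESeq2 and 9718 in the fit of all 24 libraries; RLE normalization gave 2211 and no filter 2052. The last fit leaves the change between R07 times out of its spread by construction; the cause of the other differences was not tested. With an estimated correlation 0 lists were called at 120 h, 0 for R07 against withdrawal and 0 for R07 against 0 h, in place of 20, 15 and 17; fry called 31, 12 and 0. The estimated correlation allows for genes of a list moving together, so the list calls depend on the preset one. The correlation of changes from 12 h to 120 h (0.167) was 0.160 with a prior count of 0.5, 0.200 over genes with mean log2 CPM of at least 3 and 0.166 by ranks; the cause was not tested.

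Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 13247 to 13534 genes over the course, 815 to 1905 at 4 h, 1494 to 3444 at 8 h, 1445 to 2535 at 12 h, 2681 to 4292 at 24 h, 4359 to 6194 at 36 h, 6269 to 7889 at 48 h, 9093 to 10348 at 72 h, 10677 to 11487 at 96 h and 10931 to 11891 at 120 h. The lowest counts at 4, 8 and 12 h came without 0 h library B and that at 24 h without 0 h library A. R07 against withdrawal gave 969 (without the R07 library at 72 h) to 3790 (without that at 12 h), and R07 against 0 h 0 to 2256 (without that at 12 h). The lists called ranged from 19 to 20 at 120 h, 13 to 18 for R07 against withdrawal and 15 to 20 for R07 against 0 h. The correlation ranged from 0.163 to 0.169 over the withdrawal libraries; without an R07 library it has no value.

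Of the named genes, 161 of 165 at 120 h, 112 of 150 at 24 h, 67 of 117 at 4 h, 42 of 109 for R07 against withdrawal and 2 of 35 for R07 against 0 h kept direction and call in every alternative run. None of the named genes that changed sign was called with all libraries, and the cause was not tested. Without single libraries their log2 changes ranged at 4 h for S100a8 -0.28 to 0.73, Ngp -0.79 to 0.22 and Ltf -0.70 to 0.36, and at 24 h for S100a9 -0.14 to 0.49, Irf8 -0.0927 to 0.05197, Cybb -0.21 to 0.49 and Camp -0.12 to 1.84. For R07 against 0 h they ranged for S100a8 -0.26 to 0.85, S100a9 -0.72 to 0.35, Hoxa9 -0.41 to 0.0935, Myb -0.10 to 0.14, Myc -0.21 to 0.0129, Ltf -0.29 to 0.37, Esr1 -0.16 to 0.29, Cd34 -0.24 to 0.0421 and Mki67 -0.25 to 0.0518. Myb was 0.00158 for R07 against 0 h in the fit of all 24 libraries. Depth limits the granule genes at 0 h and 4 h, which rest on few reads, and the single R07 libraries limit any statement about 1 R07 time.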

Other observations

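The test of the eosinophil genes was chosen only after the result was seen. Of 5786 genes higher at 120 h, 675 were first called higher at 4 h, 870 at 8 h, 327 at 12 h, 517 at 24 h, 515 at 36 h, 555 at 48 h, 960 at 72 h, 845 at 96 h and 522 at 120 h. Of 5885 lower genes, the numbers in the same order were 389, 758, 268, 682, 577, 800, 989, 775 and 647. Early changes went both ways by 24 h: of 1055 genes higher at 4 h, 230 were higher and 297 lower at 24 h, against 143 and 151 for independent sets, and of 662 lower genes 202 were lower and 176 higher, against 95.03 and 89.6. By 120 h fewer had turned than independent sets would give: of the 1055, 675 were higher and 265 lower, against 418 and 425, and of the 662, 389 were lower and 212 higher, against 267 and 262. From 24 h to 120 h, 1320 of 1978 higher genes were higher and 369 lower, against 783 and 796, and 1208 of 2098 lower genes were lower and 638 higher, against 845 and 831. All comparisons share the 0 h libraries, and the part of the excess that comes from the shared libraries was not separated.

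Eosinophil granule genes were high from 24 to 72 h and lower at 120 h: Prg2 had 1489 ± 251 CPM at 48 h and 41.7 ± 2.75 CPM at 120 h, and Epx 13.9 ± 3.83 and 0.211 ± 0.0542 CPM. From 48 to 96 h Prg2 changed by -2.86 and Epx by -3.20 on the log2 scale, while the eosinophil genes Ear2 and Siglecf changed by 3.55 and 0.77; Ear2 and Prg2 were 27.2 standard errors apart. Over the 20 withdrawal libraries Ear2 correlated by 0.668 with the mean of Prg2, Prg3 and Epx and by 0.893 with the mature neutrophil genes, so another source of Ear2 could give that gap, and another source of Siglecf was not tested. Eosinophils of one fixed profile in the culture, eosinophils that mature there, and a step of withdrawal in which cells express these genes for a time all stay open.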
